A study of Homo sapiens with 4 samples.

How the data were processed

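Exosomal RNA of MDA-MB-231 cells, an established human breast cancer line, was measured on 4 arrays of 1 colour each. Per the labels, cells were sorted by the surface proteins CD44 and CD24, exosomes were purified from culture supernatant by sequential centrifugation, and RNA was isolated with a commercial kit and purified on a second one. Exosomes are small vesicles released by cells. The titles and the sample type name 2 arrays as exosomes of breast cancer stem-like cells (BCSC) and 2 as exosomes of the remaining cells (nonBCSC). The groups follow those labels. The source label assigns the CD44-positive, CD24-negative gate to the samples titled nonBCSC, which is the other way round from how stem-like breast cancer cells are usually sorted. All signs would turn if that label, not the titles, were the right one.

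The deposited scanner files hold spot intensities on a linear scale and were made with Agilent Feature Extraction 12.0.3.1, per the file headers and the submitters' processing notes. The processed signal in them is background-subtracted and detrended within each array, per the file headers, and nothing had been done between arrays. The file headers name the build GRCh37 (hg19). The given gene table is of another build, so it was used for names only and no coordinates are given. The authors' deposited value table holds log2 values, 1 column per array, which share a single distribution and a median of 3.37. Each column tracked log2 of its own array's processed signal across 166729 probes, with Pearson correlations of 0.99958 to 0.99996. Its scale and direction were therefore settled, and the table served as an alternative. Columns with identical quantiles are what quantile normalization gives, an inference from the values, since the authors' step is not given in the sources used here. The other deposited columns used are flags, spot types, identifiers and, for 1 alternative, the median signal and its background.

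From these files, log2 of the processed signal was taken for 172429 spots that are not controls, spots marked as outliers (265 to 283 per array) were left out, and spots of a probe were averaged to 166729 probes. No spot was saturated. A probe counted as detected on an array when at least 50% of its spots were well above background. Under 50% of probes were detected on each array, so each array's 75th percentile over the 59219 probes detected on all 4 arrays was subtracted. Probes detected on both arrays of at least 1 group were tested, which left 71083 probes (42.6%). Values are thus relative to the bulk of detected signal on the same array and do not show total RNA per vesicle.

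Array accessions matched 31104 probes (18.7%) to a current gene symbol, and 12274 of these were tested, covering 10536 genes. A further 108526 custom probes (65.1%) carry no accession and stay unnamed. For gene lists, the tested probe with the highest mean stood for its gene.

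BCSC and nonBCSC exosomes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). Every adjusted p below comes from that fit unless another test is named, and SE is its standard error. The 36 gene lists, of which 34 had at least 5 measured members, were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry, a rotation test, were alternatives. Where a probe was not well above background on either array of a group, the fold is a bound. It sets the brighter group's mean against the mean, over the dim group's arrays, of the lowest scaled signal well above background or the probe's own signal, whichever is higher. An adjusted p printed beside a bound tests the fitted difference, which uses the dim group's own signals, and not the bound.

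Genes were named by a rule set before the data were examined. It takes CD44 and CD24, the genes past the threshold or, with none, the 5 smallest p in each direction, and at most 2 genes with the smallest p per list. Ribosomal RNA genes other than RNA5-8SN5 and a pair of unnamed noncoding probes were added after their values were seen. The text gives a selection of the list members, and every one whose sign turned in an alternative appears with that value.

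The alternatives were another background correction (normexp with an offset of 50), quantile normalization, the 75th percentile over all probes, the authors' table, other filters, the replicate number as a block, a variance prior with an intensity trend and robust estimation, leaving out each array, other thresholds and other list tests. The series' design text calls the exosome samples paired but does not say what a pair shares, so the fit without the block is the main one. Normexp had been planned on the mean signal, a column not used here, and ran on the median signal. All 4 arrays were on 1 slide and in 1 scan, so a slide block was not run. On the slide, nonBCSC arrays took positions 1 and 2 and BCSC arrays positions 3 and 4, so position and group cannot be told apart.

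The fit was tested on simulated data with the real means of 71070 probes, of which 200 were changed. Each probe's spread was drawn at random from the fit's variance prior, whatever its brightness. Of 50 probes changed 2-fold, 0% were called, against 32% at 4-fold, 70% at 8-fold and 86% at 16-fold. With no change, 0 probes were called. When 7107 probes were changed 4-fold, 94.6% were called. In the real data the SD of differences was 0.77 in the dimmest of 10 classes by brightness and 0.20 in the brightest. The simulated rates are therefore for an idealised case and need not hold for dim probes. Only 2 arrays per group limit the precision. No label says that they come from separate cultures, so p-values measure the spread between these arrays, which may be technical. Figures were drawn with matplotlib.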

Results

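RNA from exosomes of sorted MDA-MB-231 breast cancer cells was hybridised to arrays for long noncoding and messenger RNA, with 2 arrays for the stem-like fraction (BCSC) and 2 for the remaining cells (nonBCSC). The comparison asks which RNAs differ between the vesicles of the 2 fractions. Between 70360 (42.2%) and 76027 (45.6%) of 166729 probes were well above background per array. The median processed signal was 7.58 on nonBCSC 1, 11.1 on nonBCSC 2, 10.7 on BCSC 1 and 12.1 on BCSC 2. The spike-in controls were also dimmest on nonBCSC 1, with a mean log2 signal of 10.6 against 11.2 to 11.3 on the other arrays. Across probes, BCSC 1 and BCSC 2 correlated at 0.986 (Pearson) and nonBCSC 1 and nonBCSC 2 at 0.979. NonBCSC 2 correlated with the BCSC arrays at 0.985 and 0.984, more closely than with nonBCSC 1.

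The sort markers come first. CD44, a hyaluronan receptor, was detected on all 4 arrays by both of its tested probes. Its log2 difference, BCSC minus nonBCSC, was -0.17 (SE 0.20, 95% interval -0.67 to 0.34, adjusted p = 0.820) at probe A_21_P0000152. At probe A_33_P3294509 it was -0.44 (SE 0.27, interval -1.10 to 0.23, adjusted p = 0.687). Neither passed the threshold, and both intervals include 0. This and every later sign follows the sample titles, and would turn under the source label, which gives the CD44-positive, CD24-negative gate to the samples titled nonBCSC. CD24, a mucin-like surface protein, was not well above background on any of the 4 arrays at its probe, A_33_P3369844.

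No RNA passed the threshold between BCSC and nonBCSC exosomes. The genes with the smallest p on the higher side were led by RNA5-8SN5, the 5.8S ribosomal RNA, at 5.68-fold (log2 difference 2.51, SE 0.23, adjusted p = 0.287). Among tested probes with a gene name there were 2 other ribosomal RNAs, named after their values were seen. They were 28S RNA (RNA28SN5) at 2.57-fold and 18S RNA (RNA18SN5) at 1.91-fold, both with adjusted p = 0.452. RNA18SN5 was detected on both BCSC arrays and 1 nonBCSC array, and under normexp its log2 difference was -0.03, against a median of -0.24 over all probes. RNA28SN5 was at log2 1.39 under normexp and passed there alone among its 12 alternatives (adjusted p = 1.95e-05). The normexp fit gave every probe the same standard error (0.24), so that p does not reflect this probe's own spread between arrays. The mean scaled log2 signal of the 3 ribosomal probes was -0.16 ± 0.14 in BCSC and -1.77 ± 0.12 in nonBCSC exosomes (SD, n = 2). On the lower side stood RNU11, the U11 RNA of the minor spliceosome, at 4.62-fold (log2 difference -2.21, SE 0.19, adjusted p = 0.287), and BDKRB1, a bradykinin receptor, at 3.52-fold (-1.82, SE 0.21, adjusted p = 0.402). STAM2, an adaptor of the endosomal sorting machinery, was at least 4.20-fold lower (adjusted p = 0.287), THBS4, a matrix thrombospondin, at least 2.24-fold lower (adjusted p = 0.402) and the noncoding LOC100129316 at least 1.70-fold lower (adjusted p = 0.287). These 3 were not well above background on either BCSC array. Their adjusted p belong to the fitted differences (log2 -4.32 for STAM2), which rest on those faint BCSC signals, and not to the bounds. Each of these genes, from RNA5-8SN5 to LOC100129316, was tested by 1 probe. LOC100129316 has 3 probes on the array, and its others were not detected on both arrays of either group. RNA5-8SN5, RNU11 and STAM2 did pass under normexp and with a trended robust prior. Under normexp their log2 differences were smaller, at 1.05, -1.20 and -1.19, so these sizes hold for the processed signal only. With 1 array left out the log2 differences were 2.29 to 2.72, -2.28 to -2.14 and -4.87 to -3.78. Without a nonBCSC array, the spread in the fit comes from the BCSC pair alone, which for STAM2 is faint signal.

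**Figure D1:**
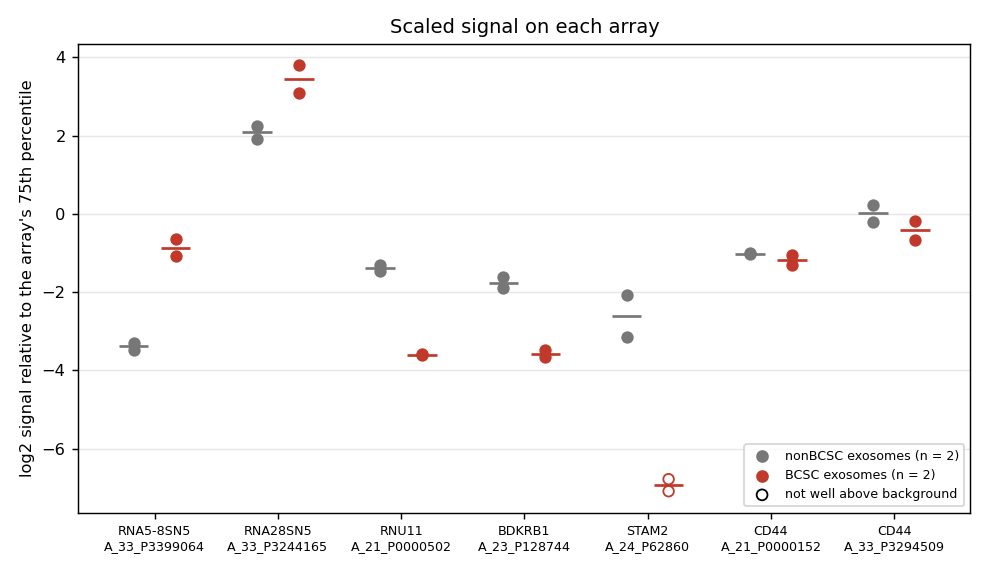
Scaled log2 signal (vertical axis) of 7 probes on each array, with nonBCSC exosomes in grey, BCSC exosomes in red, a line at each mean of 2 arrays and open circles where a probe was not well above background. RNA5-8SN5 has means of -3.38 in nonBCSC and -0.87 in BCSC exosomes, and RNU11 -1.39 and -3.59.

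The remaining genes of the higher side were faint. RAB38, a small GTPase of melanosome transport, was at least 1.55-fold higher, TTC29 at least 1.53-fold, HRC, a calcium-binding protein of the sarcoplasmic reticulum, at least 1.13-fold and HOXD1, a homeobox factor, at least 1.06-fold, each with adjusted p = 0.452. None of these 4 was well above background on either nonBCSC array, and under normexp their log2 differences turned to between -0.20 and -0.17, against the median of -0.24. TTC29 has 2 probes on the array, of which 1 was tested. Of the 17 named genes given only a bound, here and in the lists, 16 fell short of it under normexp, whose offset of 50 shrinks differences of dim probes. Among unnamed noncoding probes, A_21_P0013877 had the smallest p of all probes, at 9.47-fold higher (log2 difference 3.24, SE 0.19, adjusted p = 0.250), and A_21_P0013894 was 4.97-fold higher (2.31, SE 0.19, adjusted p = 0.287). Both were chosen after their values were seen.

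With limma, 0 of 71083 tested probes passed the adjusted threshold, and the smallest adjusted p was 0.250. At an unadjusted p under 0.05 there were 1376 probes higher and 4528 lower in BCSC exosomes, 5904 in all. A flat share of 0.05 of the tested probes is 3554. Dim probes could enter through the group in which they were detected, which can add to the count by itself. The count was 4100 of the 59219 probes detected on all 4 arrays, and 11221 of 166729 with no filter. Of the 5904, 76.7% were lower, but 46.8% with quantile normalization and 55.9% with the percentile over all probes. The share was 95.3% under normexp and 82.2% with no filter, and leaving out 1 array gave 58.0% (without nonBCSC 1) to 82.5% (without BCSC 1). The median log2 difference over all probes was -0.09, 0.00 and 0.03 under the 3 scalings. Most of the lower probes were dim. Of 10 equal classes by brightness, the dimmest held 1716 lower and 560 higher, the most in each direction. Class 2 from the dim end held 980 lower and 126 higher, and class 7 held 72 lower and 108 higher. The brightest class again held more lower (40) than higher (4), with a median of -0.16. The count of 0 rested on the arrays kept, with 70 calls without nonBCSC 1 and 1271 without nonBCSC 2. It was 44 under normexp, 10 with a trended robust prior and 1 with the strictest filter.

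**Figure D2:**
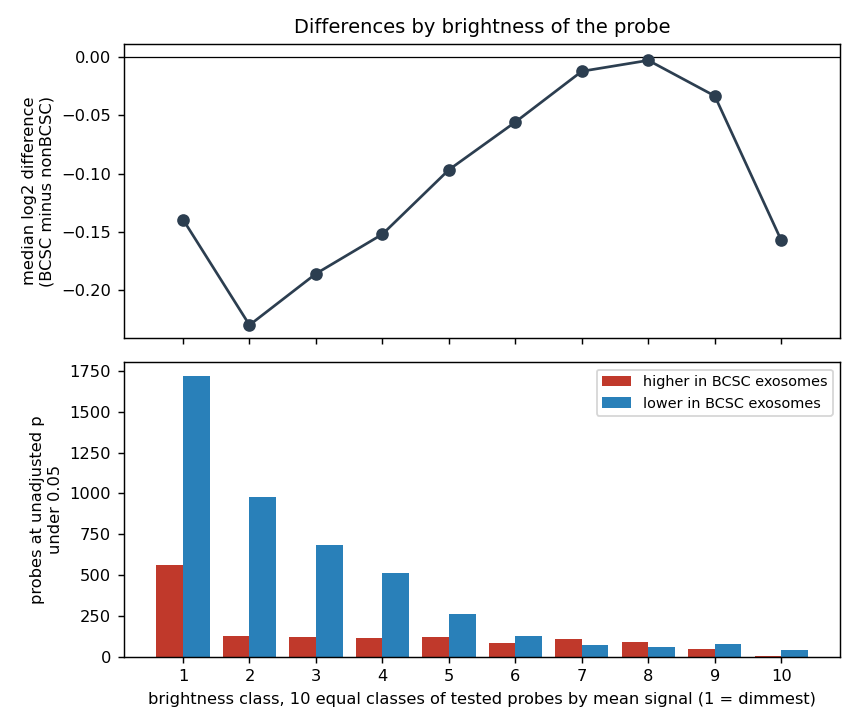
Tested probes in 10 equal classes by mean signal (horizontal axis, 1 dimmest), with the median log2 difference, BCSC minus nonBCSC (upper), and the number of probes at an unadjusted p under 0.05 that were higher (red) or lower (blue) in BCSC exosomes (lower). The median was lowest in class 2, at -0.23, and closest to 0 in class 8, and -0.16 in class 10.

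By RNA class, 9996 messenger probes (39.3% of those on the array), 8025 noncoding probes (40.9%), 47549 custom probes (43.8%) and 5513 other probes (41.9%) were tested, and 0 passed in each. At an unadjusted p under 0.05 the shares were 8.62% of messenger, 9.31% of noncoding, 7.98% of custom and 9.11% of other probes.

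Gene lists ask whether groups of related RNAs differed together. None of the 34 tested lists passed camera (smallest adjusted p = 0.697), and with an estimated correlation the smallest adjusted p was 0.927. Of 430 measured members, 0 passed over all probes. Adjusted over the list alone, 1 member passed in each of 3 lists, namely STAM2, ENO2 and TNF, and 0 in the others. That adjustment does not cover the number of lists, and none of the 3 was well above background on either BCSC array. List medians below are log2 differences less that of all genes, and 24 of the 34 changed sign in at least 1 alternative. Under normexp, 26 of 83 named probes moved by over 1.5 times in fold.

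No stem cell or mesenchymal gene passed over its list. The breast stemness list had 13 measured members and a median of -0.04, opposite in sign to its camera test. The median of that list was 0.25 without BCSC 2. ALDH1A3, a retinaldehyde dehydrogenase used to mark stem-like breast cells, was at least 2.05-fold higher (adjusted p = 0.487). Its log2 difference was 0.020 under normexp and as low as 0.75 with 1 array left out, both short of that bound. SOX9, a progenitor transcription factor, was 1.52-fold lower (adjusted p = 0.523). Mesenchymal genes had a median of -0.11, with TAGLN, an actin-binding protein, 1.88-fold lower (adjusted p = 0.462) and TWIST1, an inducer of the mesenchymal state, 1.76-fold lower (adjusted p = 0.558). The medians were 0.17 for epithelial, 0.12 for basal, 0.09 for luminal and 0.09 for matrix and invasion genes. The last 3 turned to -0.037 and -0.019 without BCSC 1 and -0.16 without nonBCSC 2. In the matrix list MMP2, a gelatinase, was at least 1.40-fold lower and ITGA3, an integrin, 1.46-fold higher, though -0.13 (log2) under normexp. ABC transporters had a median of -0.12 (0.048 with the strictest filter), with the drug efflux pump ABCB1 1.65-fold lower (adjusted p = 0.539).

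Genes of vesicle formation had a median of 0.00 over 15 members. STAM2 was the member past the threshold over the list alone (adjusted p = 5.5e-04), at a single probe. ANXA2, a membrane-binding annexin, was 1.96-fold lower and detected on 1 BCSC array (adjusted p = 0.481). Fry called this list (adjusted p = 0.0033), and without STAM2, a choice made after seeing the data, its adjusted p was 0.257. Camera did not call it (adjusted p = 0.697, and adjusted p = 0.927 with an estimated correlation).

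Ribosomal protein mRNAs had a median of -0.01 over 65 measured members, of which 7 were lower and 0 higher at an unadjusted p under 0.05. Over all 10536 genes, 665 were lower and 207 higher at that threshold. RPL3 was 2.21-fold lower, detected on 1 BCSC array (adjusted p = 0.452), and RPL28 3.38-fold lower (adjusted p = 0.504). The log2 difference of RPL28 was -0.97 without nonBCSC 1 and -2.55 without nonBCSC 2, and only the latter passed. Translation factors had a median of 0.11, with EIF3G 1.56-fold lower. Small structured RNAs had a median of -0.07, in which RN7SL1, the RNA of the signal recognition particle, was 1.64-fold higher (adjusted p = 0.549) and the vault RNA VTRNA1-3 1.55-fold lower (adjusted p = 0.554). Hosts of small nucleolar RNAs had a median of 0.18. Replication-dependent histones had a median of -0.09 over 26 members, with H2AC16 at least 1.79-fold lower (adjusted p = 0.452) and H1-5 3.79-fold lower, detected on 1 BCSC array (adjusted p = 0.486). The log2 difference of H1-5 was -2.62 without nonBCSC 1 and -1.23 without nonBCSC 2. Among cancer-related long noncoding RNAs (median -0.04), HULC was 1.73-fold lower, detected on 1 BCSC array (adjusted p = 0.482), and LINC00520 1.62-fold lower (adjusted p = 0.559).

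Metabolic and stress genes gave medians of -0.15 for glycolysis, -0.10 for nuclear-encoded oxidative phosphorylation (0.030 without nonBCSC 1), 0.04 for cholesterol synthesis, 0.33 for hypoxia (-0.063 under normexp) and -0.16 for heat shock chaperones. ENO2, a neuronal enolase, was at least 1.69-fold lower (adjusted p = 0.038 over the list alone) and COX7C, a subunit of cytochrome c oxidase, at least 1.80-fold lower (adjusted p = 0.452). In the hypoxia list PFKFB4, a regulator of glycolysis, was 1.65-fold higher (adjusted p = 0.604) and MXI1, an antagonist of MYC, 1.77-fold lower (adjusted p = 0.550). Among chaperones, the chaperonin subunit CCT3 was 1.69-fold lower, detected on 1 BCSC array. The unfolded protein response list had a median of 0.22 and the smallest camera p. Its adjusted p was 0.697, and 0.927 with an estimated correlation. TRIB3, a pseudokinase of that response, was at least 1.17-fold higher (adjusted p = 0.600), though -0.35 (log2) under normexp.

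Among signalling lists, the medians were 0.14 for NF-kB inflammation (-0.097 with no filter), 0.19 for Notch, 0.12 for Hedgehog (-0.030 under normexp), 0.03 for Wnt and -0.26 for TGF-beta. They were -0.04 for interferon response, 0.03 for p53 targets and 0.07 for immune checkpoint and antigen genes. Wnt turned to -0.0017 without BCSC 1, and p53 targets to -0.016 with quantile normalization. Without nonBCSC 1, interferon response turned to 0.040 and immune checkpoint and antigen genes to -0.038. TNF, an inflammatory cytokine, was at least 1.67-fold lower (adjusted p = 0.030 over the list alone). CSF3, a granulocyte growth factor, was 2.13-fold higher, detected on 1 nonBCSC array (adjusted p = 0.527), though -0.16 (log2) under normexp. Cell cycle lists had medians of 0.16 for S phase (-0.10 with no filter) and -0.01 for G2 and M phase, the latter opposite in sign to its camera test.

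Lists for other cell types gave medians of -0.08 for leukocytes, 0.10 for endothelium (-0.047 without nonBCSC 1), -0.01 for erythroid cells and platelets (again opposite to its test) and -0.23 for liver plasma proteins (0.041 without nonBCSC 1). In the last, FGG, a fibrinogen chain, was at least 2.01-fold lower (log2 difference -0.58 without nonBCSC 1, short of that bound) and SERPINA1, antitrypsin, 1.41-fold lower. Fibroblast markers, with 4 measured members and a median of 0.10, and mitochondrially encoded genes, with 0, were not tested.

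**Figure D3:**
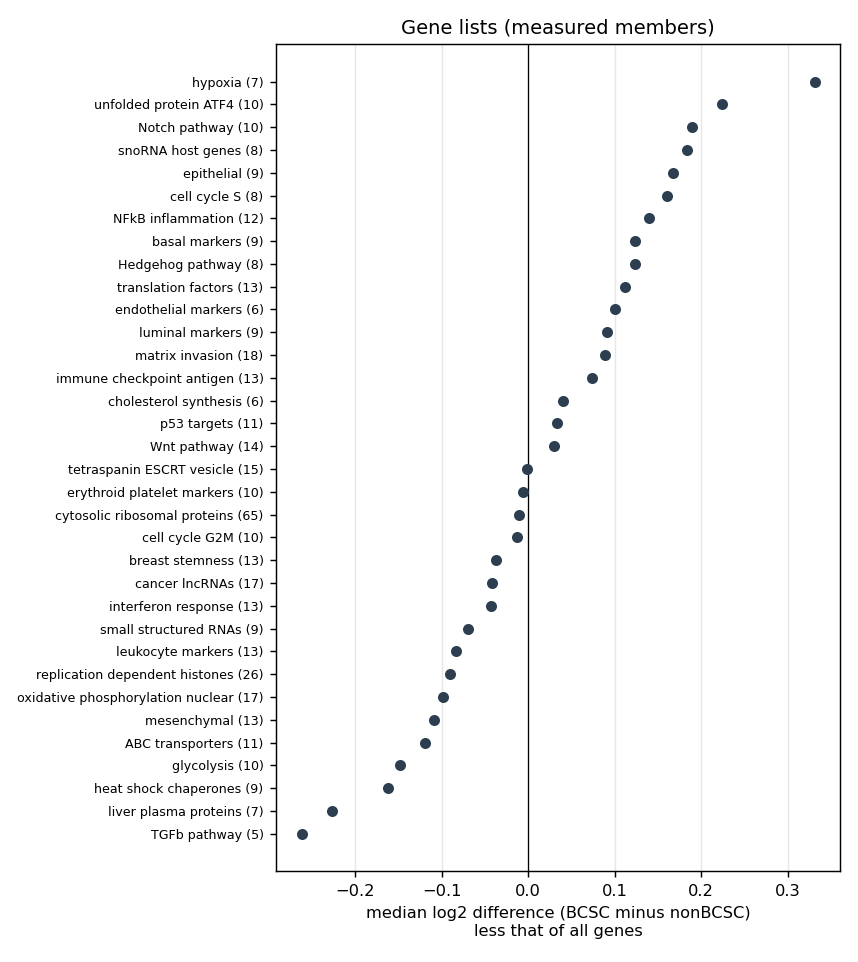
Median log2 difference, BCSC minus nonBCSC, less that of all genes (horizontal axis) for the 34 tested gene lists, with the number of measured members in brackets. Medians run from -0.26 to 0.33, and no list passed camera.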

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

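No probe passed under quantile normalization, the percentile over all probes, the authors' table, no filter on dim probes or the replicate block. Adding 2-fold to the adjusted threshold could only leave the count at 0. The count moved from 0 to 44 under normexp, 10 with a trended robust prior, 1 when a probe had to be well above background on all 4 arrays, and 1691 at an unadjusted p with 2-fold. That 1 probe, A_21_P0013877, made the noncoding count 1. Leaving out 1 array, with the lone array assumed to vary like the other group, gave 0 to 1271 calls: 0 without either BCSC array, 70 without nonBCSC 1 and 1271 without nonBCSC 2. The cause was not tested. Under normexp the fit gave all probes the same standard error, so its p-values do not reflect a probe's own spread between arrays.

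The replicate number as a block gave 0 calls and 6853 probes at an unadjusted p under 0.05, against 5904 without it. Deviations of same-numbered arrays correlated at 0.0473, so the numbers were not shown to pair arrays, though the design text calls the samples paired. A slide block was not run, since there was 1 slide.

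Camera called 0 lists in every alternative, and fry called 1, the vesicle list (adjusted p = 0.0033, but 0.257 without STAM2, chosen after seeing the data, and camera adjusted p = 0.927 with an estimated correlation). Of 34 lists, 15 kept camera's direction in the 11 alternatives of the fit that can move it (the variance prior does not enter camera) and 19 turned in at least 1. By the median, which 9 alternatives can move, 10 kept their sign and 24 turned. CD44 kept its sign and stayed short of the threshold in all 12.

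Under normexp the median over all probes was -0.24, and these log2 differences turned: TTC29 -0.20, HOXD1 -0.18, HRC -0.17, RAB38 -0.18, TRIM29 -0.33, IDI1 -0.21, CLDN4 -0.052, GP9 -0.30, GLI2 -0.13, XBP1 -0.24, ITGA3 -0.13, CSF3 -0.16, RBPJ -0.24, SNHG15 -0.34, SNHG3 -0.10, EEF1G -0.35, TRIB3 -0.35 and RNA18SN5 -0.025. Less that median, 5 of the 18 were still turned. The normexp offset of 50 exceeds the median processed signal of every array (7.58 to 12.1). It draws dim probes toward that median by construction, so a turn that stops short of the median does not show a reversed difference. The 5 past it were TRIM29, GP9, SNHG15, EEF1G and TRIB3, at -0.058 to -0.104 less that median. Such a pull alone would not carry them past it, and whether they reversed was not tested. Leaving out 1 array gave both signs for SREBF2 (-0.60 to 0.11), IDI1 (-0.066 to 0.44), MFAP5 (-0.017 to 0.35), SNHG3 (-0.024 to 0.57) and WNT10B (-0.51 to 0.0091). Less each setting's median over all probes, SREBF2 and WNT10B were still turned and the other 3 were not. The cause was not tested. RNA5-8SN5, RNU11, STAM2, A_21_P0013894 and A_21_P0013877 kept their sign throughout. With all 4 arrays they passed under normexp and with a trended robust prior, and A_21_P0013877 also with the strictest filter. Signal over background limits the dim genes given as bounds.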

Other observations

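The tests of ribosomal RNA and of agreement between probes were chosen after their results had been seen, and those of the excess of lower probes and of the splits before.

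The 3 ribosomal RNA probes had a mean log2 difference of 1.60 toward BCSC exosomes. It was 1.69 without the dim array nonBCSC 1, which argues against that array as the whole cause. Quantile normalization, the percentile over all probes and the authors' table gave 1.72 to 1.75. They moved the median over all probes only from -0.09 to between 0.004 and 0.026. Less that median, the mean difference of the 3 probes was 1.69 to 1.75 under these settings and 1.05 under normexp. A shift common to all probes of an array would not leave such a rise over the median. These values therefore argue against such scaling, for these 3 probes. Under normexp the mean was 0.81, from 1.39 for RNA28SN5, 1.05 for RNA5-8SN5 and -0.025 for RNA18SN5. Carry-over of cellular RNA that moves all messenger RNAs alike stays open. The median of ribosomal protein mRNAs, -0.010 less that of all genes, would lie near 0 either way. Over the alternatives that median ran from -0.13 to 0.090, so carry-over that lifts these mRNAs over other genes was not seen. No single ribosomal probe passed the adjusted threshold. A difference between the vesicles of the fractions may remain as a hypothesis, and so may carry-over, slide position or chance.

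The excess of lower probes at an unadjusted p under 0.05 (76.7%) was weighed against the background of nonBCSC 1 and the scaling. Without nonBCSC 1 the lower share was 58.0%, against 71.3% to 82.5% without any other array, so a raised scaled background on that dimmest array may contribute. Under normexp, another background correction, the share rose to 95.3%. Normexp adds an offset of 50 on every array. The 75th percentile of processed signal was 152 on nonBCSC 1 against 272 to 346 on the other arrays. After scaling, the offset therefore weighs most on nonBCSC 1 and lifts dim probes there by construction. The share under normexp thus cannot decide on the background. The scaling percentile stays open, since quantile normalization centres the differences and so sets its share (46.8%) near balance by construction. A biological part was not excluded.

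Large single-probe differences were set against a further probe of the same gene, since chance or probe-specific signal would give no agreement. The 2 probes can be taken in several ways, and 4 were computed. With the probe of smallest p (under 0.01) and the brightest other, 33 of 64 genes agreed in sign (51.6%, exact 95% interval 38.7 to 64.3). The next smallest p in place of the brightest gave 53.1%, the order of probe names 18 of 36 genes, and the brightest 2 probes 66.7% of 9 genes. In each, the further probe's median difference in the first's direction was at most 0.090 times the first's. Across 1494 genes, which are not independent replicates, the differences of 2 probes correlated at 0.01. Most leading genes of the comparison have 1 probe, so chance or probe-specific signal may lie behind any of them.

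The 4 arrays can be split into pairs in 3 ways, too few for a share under 0.05. The real split gave 5904 probes at an unadjusted p under 0.05, 1 of the 3 splits with as many, and the highest of the other splits gave 2336. All 3 used the same tested probes, which were kept by detection on both arrays of a real group. That filter can favour the real split, so these counts are not on equal terms.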
